A study of Mus musculus with 9 samples.

How the data were processed

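RNA sequencing was performed on smooth muscle cells that had been sorted from mouse lung by fluorescence. The 9 libraries formed 3 groups of 3. BSMC were bronchial smooth muscle cells from mice labelled NVSMC-effector, which carried Chrm2 and Acta2-CreER drivers and an R26-GFP reporter. PASMC were pulmonary arterial smooth muscle cells from mice labelled ASMC-effector, which carried Cspg4 and Acta2-CreER drivers and the same reporter. The group total_SMC held smooth muscle cells of the whole lung, venous cells included, from mice with an Acta2-GFP transgene. The labels of all 9 libraries gave tamoxifen at 0.75 mg per 10 g body weight for 3 days from a 20 mg/mL stock in corn oil. RNA was purified with a column kit that includes a DNase step, and at most 10 ng went into each SMART-Seq v4 library.

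Per the labels, the authors named Trimmomatic 0.39, STAR 2.7.11a, Picard 3.1.1, featureCounts 2.0.4, DESeq2 1.36.0 and the build mm39, without the role or order of each. The deposited values, recorded here with the unit score, were normalized read counts per gene, rounded to whole numbers, and not the raw counts that the plan had assumed. This was read from the values themselves: in 3 columns certain whole numbers never occurred, and in the other 6 columns certain whole numbers occurred 1.85 to 2.36 times as often as their neighbours, where a pair of counts mapped to 1 value. A library factor was recovered from that spacing, and value divided by factor is called implied reads below. On simulated data the recovered factors were off by at most 0.011%. The table held 21049 genes, of which 15963 were protein coding and 3103 were long non-coding RNA, and no mitochondrially encoded gene. Coordinates are those of the table. Exon lengths came from GENCODE vM21 by gene identifier, for 96.7% of genes.

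Depth was read as implied reads per library, 6.39 to 10.02 M. No confidence interval was computed for single values, since spread between libraries is given instead. The sequenced molecules carried no identifiers, so counting error alone understates the noise, except in some of the densest genes, whose spread lay below it. No pair of libraries of the same group was a copy of another: the chi-square per gene lay between 5.4 and 22.7 over 9 pairs.

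Genes with a value of at least 10 in at least 3 libraries were kept, which left 15647. Values were transformed as log2 of value plus 1, and all 9 libraries entered 1 limma fit of 3 group means (lmFit, then eBayes with trend and robust options; limma 3.58.1, R 4.3.3). P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene is called changed, higher or lower at an adjusted p under 0.05. The labels do not say whether replicates came from separate animals, so p-values measure the spread between samples. Each pairwise comparison was made, and genes of 1 group called in the same direction against both of the others were counted. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

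Of 37 gene lists fixed before the data were examined, 36 had at least 4 measured members and were tested; the list of mitochondrially encoded genes had 0 members in the table. Each list was tested in each comparison with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, giving 108 tests of which 51 passed. With an estimated correlation 0 of the 108 passed, and that p stands beside each list call in the report. Lists overlap, and a gene in several lists was counted in each.

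Genes to name were chosen by a rule also fixed before the data were examined. It takes Acta2, Myh11, Chrm2 and Cspg4 in every comparison, and the 8 largest called changes in each direction among genes without overlap between the groups and with a mean of at least 100 in the higher group. It adds up to 3 called members of a list in each direction, the 2 most abundant members of a list without a call, and the 10 largest changes of each group of genes set apart from both other groups. Predicted genes and pseudogenes were left out, and the text names a part of this set. Gt(ROSA)26Sor and its neighbours Thumpd3 and Setd5 were chosen after their values were seen. So were Hhip, Lgr6 and Myocd, where the rule did not take them.

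The test was tried on simulated values with 100 genes changed 2-fold and another 100 changed 4-fold in each comparison. It recovered 43%, 33% and 42% of 2-fold changes and 100%, 100% and 99% of 4-fold changes, for PASMC against BSMC, total_SMC against PASMC and total_SMC against BSMC. Among unchanged genes it made 14, 1 and 10 false calls. All simulated libraries were drawn at the same depth and then multiplied by the library factors. They therefore held shifts between libraries that the normalized values lack. The same dispersion was used for every gene and group, although BSMC varied more. These rates thus describe the simulated setting and do not measure the power or error of the test on the deposited values. Of the alternatives fixed before the data were examined 19 were run, and 4 were added after the values had been seen: another scaling by cyclic loess, implied reads without scaling, a fit without genes near a counting limit, and a fit without the 2 BSMC libraries of lowest depth. A planned DESeq2 test on recovered reads was not run, since in libraries with a factor under 1 a pair of counts maps to 1 value.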

Results

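Gene expression was measured by RNA sequencing in smooth muscle cells sorted from mouse lung, to compare the pulmonary smooth muscle types directly. Bronchial cells (BSMC), pulmonary arterial cells (PASMC) and total pulmonary smooth muscle cells with the venous cells included (total_SMC) were each measured in 3 libraries. Each group came from its own mouse line, and total_SMC carried an Acta2-GFP transgene in place of the R26-GFP reporter. Cell population, mouse line and sort therefore cannot be told apart in any comparison. Values are normalized read counts (summed over a list as counts per M, CPM), given as mean ± SD with n = 3 per group, and fold changes are on the log2 scale with the standard error (SE) of the fit. Implied depth was 7.62 ± 1.53 M reads in BSMC, 9.43 ± 0.55 M in PASMC and 9.54 ± 0.53 M in total_SMC. Within BSMC it was 7.14 M in replicate 1, 9.33 M in replicate 2 and 6.39 M in replicate 3. The normalized totals ran from 7.98 to 9.41 M. A gene named below as higher or lower had no overlap between the libraries of the groups compared, unless stated, and called genes had an adjusted p under 0.05 in limma.

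The first principal component held 50.3% of the variance and the second 23.3%. BSMC lay between -123.6 and -68.1 on the first, against 33.9 to 42.9 for PASMC and 61.3 to 68.6 for total_SMC. The BSMC library nearest to PASMC was replicate 2, at -68.1. Its chi-square per gene was 18.9 and 22.7 against the other BSMC libraries and 20.7 to 24.1 against PASMC. The second set PASMC, between -69.9 and -63.5, apart from total_SMC, between 51.5 and 61.4.

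**Figure D1:**
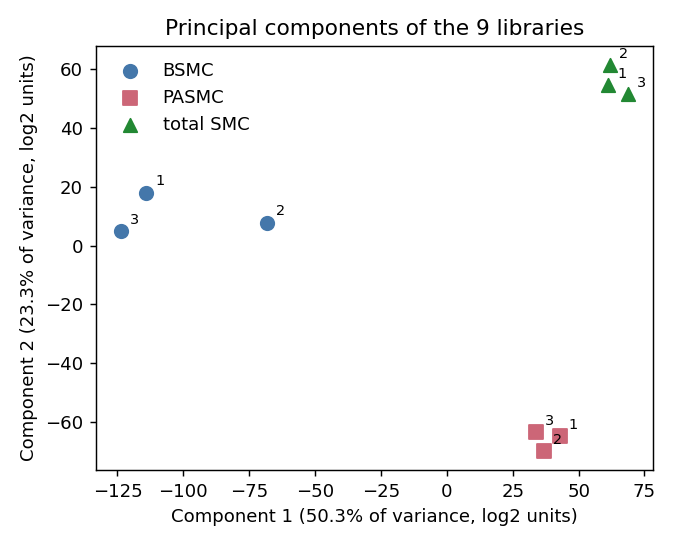
Scores of the 9 libraries on the first 2 principal components of log2 normalized counts, 1 point per library, coloured by group. The BSMC libraries spread from -123.6 to -68.1 on the first component, and the PASMC and total_SMC libraries separate on the second.

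Contractile genes were abundant in all groups. Myh11, the smooth muscle myosin heavy chain (ENSMUSG00000018830, mm39 chromosome 16, 14012399 to 14109236), was at 10536 ± 1196 in BSMC, 11958 ± 674 in PASMC and 10927 ± 1263 in total_SMC, without a call in any comparison. Acta2, smooth muscle actin and part of the driver or transgene of every line (ENSMUSG00000035783, chromosome 19, 34218490 to 34232990), was at 3948 ± 628, 3290 ± 201 and 3017 ± 109. It was lower in total_SMC than in BSMC (-0.38, SE 0.12, adjusted p = 0.0281) and was not called between PASMC and BSMC (-0.25, adjusted p = 0.145). Both genes were among 235 tested genes with at least 1 implied read per exonic base, here called near the counting limit. So were 9 of the 34 contractile genes tested. If counts are capped there, group differences shrink, so a missing call or similar values do not show equal expression. Over all genes, the median ratio of variance to mean within groups was 22.97 at 0.2 to 0.4 reads per base and 1.18 above 1.5. Myh11 did not follow this in BSMC, with an SD of 2516 implied reads where counting alone gives 99.3. Chrm2, the muscarinic acetylcholine receptor named in the BSMC line (ENSMUSG00000045613, chromosome 6, 36365019 to 36505349), was at 164 ± 54.6 in the libraries labelled BSMC, 327 ± 111 in those labelled PASMC and 305 ± 57.9 in total_SMC. Cspg4, the NG2 proteoglycan of mural cells named in the PASMC line (ENSMUSG00000032911, chromosome 9, 56772317 to 56807154), was at 1514 ± 244, 2003 ± 370 and 555 ± 211, and was not called between PASMC and BSMC (0.40, adjusted p = 0.268).

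The Acta2 call between total_SMC and BSMC was lost without BSMC replicate 1 (adjusted p = 0.0759), BSMC replicate 3 (0.093), or total_SMC replicate 1 (0.0646), 2 (0.0836) or 3 (0.0615). Between PASMC and BSMC, Acta2 passed without BSMC replicate 2 (-0.38, adjusted p = 0.0102). On implied reads without scaling its fold between total_SMC and BSMC was -0.19 (adjusted p = 0.167), and the library factors alone would give -0.18 in genes at the limit. Over all alternatives its adjusted p ran from 0.00156 to 0.529 and from 0.0102 to 0.999 in these comparisons.

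Gt(ROSA)26Sor, the non-coding gene of the locus that carries the reporter in the driver lines (ENSMUSG00000086429, chromosome 6, 113043843 to 113054294), was chosen after its values were seen. It was at 770.3 ± 120.0 in BSMC, 742 ± 124 in PASMC and 149.7 ± 56.0 in total_SMC. It was lower in total_SMC than in PASMC (-2.36, adjusted p = 0.000116) and than in BSMC (-2.41, adjusted p = 3.81e-05). Its neighbours Thumpd3 and Setd5 were not called in any comparison.

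**Figure D2:**
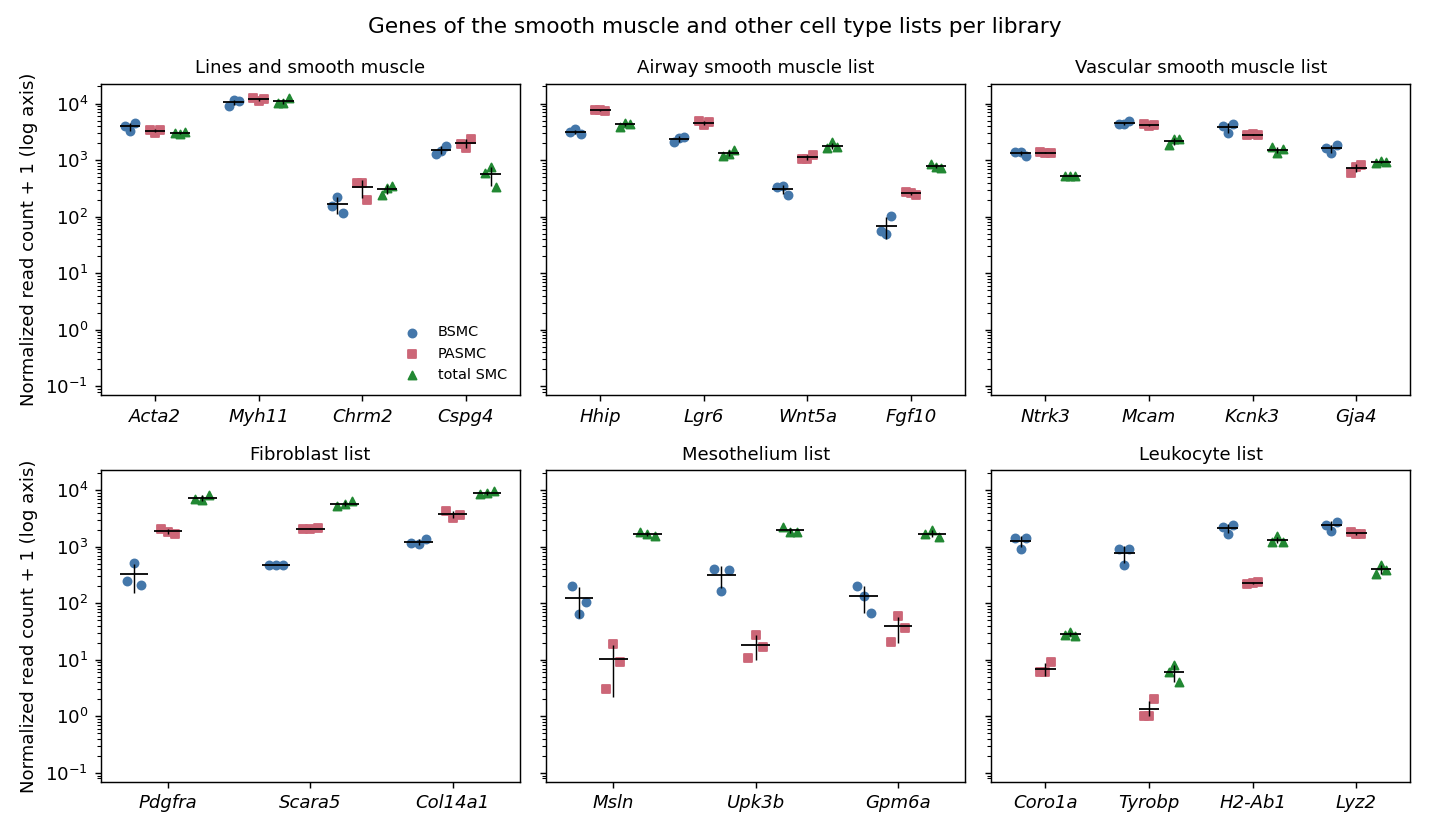
Normalized read count plus 1, on a log axis, of marker genes in the 9 libraries, 1 point per library with the group mean and SD. Coro1a and Tyrobp are high in BSMC, Msln and Upk3b in total_SMC, and Hhip in PASMC.

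The first comparison set the arterial against the bronchial cells. Libraries labelled PASMC had higher lists of Hedgehog and airway smooth muscle genes than libraries labelled BSMC, and higher lists of fibroblast and basement membrane genes, by camera at the preset correlation. With an estimated correlation none of these passed (adjusted p = 0.15, 0.342, 0.399 and 0.0698). Hhip, the Hedgehog-binding antagonist (ENSMUSG00000064325, chromosome 8, 80692480 to 80784635), was at 7597 ± 193 in PASMC and 3161 ± 298 in BSMC (log2 fold change 1.27, SE 0.10, adjusted p = 9.59e-06). Scara5, a ferritin receptor of adventitial fibroblasts, was at 2106 ± 57.7 against 478 ± 5.6 (2.14, SE 0.11, adjusted p = 3.64e-07). Leukocyte genes ran the other way: Coro1a, an actin regulator of blood cells, was at 1268 ± 296 in BSMC and 6 ± 1.7 in PASMC (-7.50, SE 0.30, adjusted p = 7.42e-08). Of 15647 genes tested, 3451 were changed (22.1%), 2062 higher in PASMC and 1389 lower, and 1931 of them by at least 2-fold.

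Of 15 airway smooth muscle genes tested, 6 were higher in the libraries labelled PASMC and 0 lower, and 8 were called when adjusted over the list alone. The camera test gave an adjusted p of 0.0151, and adjusted p = 0.342 with an estimated correlation. Besides Hhip, these included Wnt5a, a Wnt ligand of airway mesenchyme (1112 ± 104 against 306 ± 58.8, 1.87), and Fgf10, a growth factor that drives epithelial branching (258 ± 14.5 against 68.3 ± 29.4, 1.98). Lgr6, an R-spondin receptor of airway smooth muscle, was at 4528 ± 374 in PASMC and 2387 ± 267 in BSMC (0.93). Of 12 Hedgehog genes 6 were higher and 0 lower, 10 adjusted over the list alone (camera adjusted p = 0.000176; adjusted p = 0.15 with an estimated correlation), among them the transcription factor Gli2 (1.69). Of 11 genes of alveolar duct myofibroblasts 7 were higher and 0 lower, 10 adjusted over the list alone (camera adjusted p = 3.12e-05; adjusted p = 0.0698 with an estimated correlation), with Pdgfra, the platelet-derived growth factor receptor of fibroblasts, at 1874 ± 178 against 325 ± 170 (2.64). Chrm2 was higher in PASMC by 0.98 (SE 0.31, adjusted p = 0.0433), with 1 PASMC library (199) inside the BSMC range of 115 to 223. Summed fibroblast RNA moved with these genes, 8795 ± 540 CPM in PASMC and 7627 ± 714 in BSMC, but the libraries overlapped (8247 to 9326 against 6922 to 8350). Of the 24 fibroblast genes 8 were near the counting limit.

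That Chrm2 call was lost without BSMC replicate 1 (adjusted p = 0.108) or 3 (0.126), PASMC replicate 1 (0.16) or 2 (0.15), or total_SMC replicate 1 (0.0537), 2 (0.0644) or 3 (0.0618), within a range of 0.00963 to 0.535 over all alternatives. The airway list call was lost without BSMC replicate 2 (adjusted p = 0.158; range over alternatives 2.81e-05 to 0.158).

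Matrix genes were higher in PASMC as groups. Of 22 basement membrane genes 15 were higher and 0 lower, 16 adjusted over the list alone (camera adjusted p = 2.51e-08; adjusted p = 0.0698 with an estimated correlation). Lamc1, a laminin chain, was at 3272 ± 257 against 1348 ± 151 (1.28), and Col4a6, a collagen of basement membranes, at 3092 ± 647 against 1072 ± 200 (1.52). Fibroblast genes numbered 14 higher and 0 lower of 24, 14 adjusted over the list alone (camera adjusted p = 0.00032; adjusted p = 0.399 with an estimated correlation). Among 18 fibrillar and associated collagens 10 were higher and 1 lower, 12 adjusted over the list alone (camera adjusted p = 0.000115; adjusted p = 0.355 with an estimated correlation), with Col14a1 higher by 1.61 and Col8a1 lower by -1.15. Elastic fibre genes gave 9 higher and 0 lower of 21, 11 adjusted over the list alone (camera adjusted p = 0.0151; adjusted p = 0.381 with an estimated correlation), led by Fbn1, the microfibril protein fibrillin (1.11). That list call was lost without BSMC replicate 2 (adjusted p = 0.158) and after cyclic loess normalization (0.0769), within a range of 2.81e-05 to 0.158. Of 38 axon guidance genes 14 were higher and 0 lower, 18 adjusted over the list alone (camera adjusted p = 0.000115; adjusted p = 0.279 with an estimated correlation), among them Plxna2, a semaphorin receptor (2.16), and Robo2, a Slit receptor (2.74).

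Genes of blood and pleural cells were higher in BSMC. All leukocyte genes tested but Lyz2 were called, 19 of 20, and 20 adjusted over the list alone (camera adjusted p = 1.32e-25; adjusted p = 0.0698 with an estimated correlation). Their summed level was 2085 ± 446 CPM in BSMC and 335.5 ± 13.9 in PASMC. H2-Ab1, an antigen-presenting molecule, was at 2147 ± 384 against 227 ± 9.0 (-3.22), and Tyrobp, an adaptor of myeloid receptors, at 772 ± 249 against 0.3 ± 0.6. Jchain, the joining chain of secreted antibodies, was at 904 ± 400 in BSMC and listed at 0 in all PASMC libraries, and Igha, the IgA heavy chain, was at 1988 ± 355 against values of 1, 0 and 0. Reads of immunoglobulin segments can be shared between related genes. All 6 erythroid genes tested were higher in BSMC, 6 adjusted over the list alone (camera adjusted p = 5.06e-07; adjusted p = 0.108 with an estimated correlation), with Hbb-bs, an adult globin, at 219 ± 81.5 against 6.7 ± 5.0. Mesothelium gave 6 of 8 genes higher in BSMC, 6 adjusted over the list alone (camera adjusted p = 0.00034; adjusted p = 0.342 with an estimated correlation), and Upk3b, a uroplakin of mesothelium, was at 320 ± 134 against 17.7 ± 8.6. Endothelial genes gave 9 higher in BSMC and 0 lower of 23, 13 adjusted over the list alone (camera adjusted p = 0.00253; adjusted p = 0.355 with an estimated correlation), and interferon response genes 6 and 0 of 26, 6 adjusted over the list alone (camera adjusted p = 0.00652; adjusted p = 0.342 with an estimated correlation).

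Of 19 epithelial genes 10 were higher in PASMC and 3 lower, 14 adjusted over the list alone (camera adjusted p = 0.0482; adjusted p = 0.514 with an estimated correlation). Surfactant protein D (Sftpd) was at 625 ± 27.8 in PASMC and 201 ± 47.8 in BSMC (1.66), and the club cell secretoglobin Scgb3a2 at 533 ± 129 against library values of 63, 138 and 69 (2.61). Ager and Hopx, markers of flat alveolar cells, fell by 1.32 and 1.87. The list call was lost without BSMC replicate 2 (adjusted p = 0.165) or PASMC replicate 1 (0.0753) or 3 (0.0948), with the replicate number as a block (0.0572), array weights (0.101) or the stricter filter (0.0827) and on implied reads (0.0513), within a range of 0.00737 to 0.165 over all alternatives. Chondrocyte genes gave 3 higher and 0 lower of 7, 4 adjusted over the list alone (camera adjusted p = 0.0383; adjusted p = 0.342 with an estimated correlation), with the cartilage collagen Col2a1 at 21 ± 5.3 against 0.3 ± 0.6. This call was lost without BSMC replicate 2 (adjusted p = 0.165) or PASMC replicate 1 (0.103), 2 (0.221) or 3 (0.236), with the replicate number as a block (0.0507) and with array weights (0.106), in a range of 0.00155 to 0.236. Col10a1, the collagen of hypertrophic cartilage, was at 100 ± 58.9 in PASMC and 1.3 ± 1.5 in BSMC.

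Contractile genes, 9 of the 34 near the counting limit, gave 5 higher and 1 lower, 4 adjusted over the list alone, and did not pass camera (adjusted p = 0.403). Their median was -0.21, their mean 0.02 and the direction of the test negative, and the median was 0.03 on implied reads without scaling. The test passed in 2 of 22 alternatives, quantile normalization (adjusted p = 0.0372) and cyclic loess (0.047), in a range of 0.0372 to 0.941. Immediate early and dissociation response genes gave 8 higher and 1 lower of 26, 10 adjusted over the list alone (camera adjusted p = 0.152). That test passed in 4 of 22 alternatives, among them the one without BSMC replicate 3 (adjusted p = 0.00679), in a range of 7.65e-07 to 0.881. Myocd, the coactivator of contractile genes, was at 1045 ± 293 in PASMC and 399 ± 107 in BSMC (1.39, adjusted p = 0.00533). Arterial and vascular genes gave 5 higher and 2 lower of 20, 10 adjusted over the list alone (camera adjusted p = 0.835), with a median of 0.02 that was -0.11 after cyclic loess. Among them Jag1, a Notch ligand, was higher (1.26) and Gja4, a connexin of arteries, lower (-1.15). Nuclear genes of oxidative phosphorylation numbered 0 higher and 9 lower of 62, 22 adjusted over the list alone (camera adjusted p = 2.1e-09; adjusted p = 0.473 with an estimated correlation). Ribosomal protein genes gave 0 higher and 8 lower of 76, 0 adjusted over the list alone (camera adjusted p = 1.21e-10; adjusted p = 0.514 with an estimated correlation). Depth moved with these lists: their mean log2 value was 9.30 and 9.36 in BSMC replicates 1 and 3, the least deep libraries, and 8.84 in replicate 2.

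The count of 3451 rested on single libraries: it was 1827 without BSMC replicate 1, 6364 without 2 and 2299 without 3, and 1701 and 1977 without PASMC replicates 1 and 2. In 5503 genes (35.2%, where chance gives 10%) the groups did not overlap. On implied reads without scaling, where the median of all genes moved to 0.28, the calls were 1897 higher and 685 lower, and after quantile normalization 2017 and 2072.

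The second comparison set total smooth muscle cells, venous cells included, against the arterial cells. By camera at the preset correlation, lists of contractile, arterial and striated muscle genes were lower in total_SMC, and lists of fibroblast, mesothelial, endothelial, leukocyte and erythroid genes were higher. None of these passed with an estimated correlation (adjusted p = 0.0953 to 0.38), and in the contractile list 21 of 34 genes were not called. Ntrk3, a neurotrophin receptor, was at 526 ± 10.4 in total_SMC and 1349 ± 28.3 in PASMC (-1.36, SE 0.12, adjusted p = 2.36e-05). Msln, the mesothelial surface protein mesothelin (ENSMUSG00000063011, chromosome 17, 25967587 to 25973352), was at 1701 ± 127 against 9.3 ± 8.1 (7.73, SE 0.57, adjusted p = 1.05e-05). Of the genes tested 2539 were changed (16.2%), 1470 higher in total_SMC and 1069 lower, and 1656 by at least 2-fold.

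Of 34 contractile genes 0 were higher and 13 lower in total_SMC, 15 adjusted over the list alone (camera adjusted p = 6.51e-10; adjusted p = 0.269 with an estimated correlation). Ppp1r12a, the regulatory subunit of myosin phosphatase, was at 2120 ± 214 against 4450 ± 269 (-1.07), Lmod1, an actin nucleator, at 1488 ± 244 against 3071 ± 219 (-1.06), and Actn1, an actin cross-linker, fell by 1.12. The contractile genes summed to 10610 ± 625 CPM in total_SMC and 14070 ± 729 in PASMC. Arterial and vascular genes gave 1 higher and 10 lower of 20, 16 adjusted over the list alone (camera adjusted p = 3.29e-05; adjusted p = 0.0953 with an estimated correlation), among them Aoc3, an amine oxidase of vascular muscle (-1.29), and Cspg4 (-1.91, SE 0.26, adjusted p = 0.000441). The list of cardiac muscle in the pulmonary vein wall gave 0 higher and 16 lower of 27, 19 adjusted over the list alone (camera adjusted p = 2.41e-12; adjusted p = 0.251 with an estimated correlation). Its members include the troponin Tnnt2, at 368 ± 47.0 against 892 ± 57.1 (-1.28), and Cox6a2, a respiratory subunit of striated muscle, at 4.3 ± 0.6 against 58.7 ± 21.1. Chrm2 (-0.05, adjusted p = 0.951) was not called. Summed fibroblast RNA was 11010 ± 578 CPM in total_SMC and 8795 ± 540 in PASMC, and moved with the fall of these muscle lists.

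Calcium, cyclic nucleotide, glycolysis and immediate early lists each had more genes lower in total_SMC than higher. Calcium handling genes gave 6 higher and 10 lower of 42, 24 adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.28 with an estimated correlation), with Casq1, a calcium store protein, at 240.0 ± 95.1 against 889 ± 67.6 (-1.97) and P2rx1, an ATP-gated channel, lower by -1.33. This list call was lost without total_SMC replicate 1 (adjusted p = 0.0569) and with the stricter filter (0.0525), in a range of 0.0111 to 0.0569. Cyclic nucleotide genes gave 3 higher and 7 lower of 37, 16 adjusted over the list alone (camera adjusted p = 0.00803; adjusted p = 0.269 with an estimated correlation), with the cyclase Adcy5 lower (-1.33) and the phosphodiesterase Pde9a higher (1.29). Glycolysis genes gave 1 higher and 9 lower of 26, 11 adjusted over the list alone (camera adjusted p = 0.000507; adjusted p = 0.269 with an estimated correlation), among them Slc2a4, the insulin-responsive glucose transporter (-1.28). Immediate early genes gave 1 higher and 6 lower of 26, 8 adjusted over the list alone (camera adjusted p = 0.00285; adjusted p = 0.496 with an estimated correlation). Atf3, a stress-induced transcription factor, was at 461 ± 66.0 in total_SMC, 1555 ± 445 in PASMC and 489 ± 121 in BSMC.

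Mesothelial genes were higher in total_SMC without exception, 8 of 8, and 8 adjusted over the list alone (camera adjusted p = 9.46e-11; adjusted p = 0.216 with an estimated correlation). They summed to 861 ± 93.7 CPM in total_SMC, 41.5 ± 10.7 in PASMC and 139 ± 57.5 in BSMC. Fibroblast genes gave 8 higher and 2 lower of 24, 13 adjusted over the list alone (camera adjusted p = 0.00114; adjusted p = 0.38 with an estimated correlation), with Pdgfra at 7386 ± 813 against 1874 ± 178 (1.98) and Scara5 higher by 1.46. Endothelial genes gave 13 higher and 1 lower of 23, 17 adjusted over the list alone (camera adjusted p = 1.3e-06; adjusted p = 0.251 with an estimated correlation), with Kdr, the endothelial growth factor receptor, at 1112 ± 70.4 against 277 ± 82.0 (2.04). Of 20 leukocyte genes 11 were higher and 1 lower, 14 adjusted over the list alone (camera adjusted p = 3.31e-07; adjusted p = 0.269 with an estimated correlation). The lower gene was Lyz2, a lysozyme of macrophages and alveolar cells, at 404 ± 76.4 against 1734 ± 94.9, and near the counting limit. All 6 erythroid genes were higher, 6 adjusted over the list alone (camera adjusted p = 6.77e-05; adjusted p = 0.251 with an estimated correlation), with Hba-a1 at 35 ± 13.1 against 2.3 ± 0.6. Epithelial genes gave 3 higher and 9 lower of 19, 14 adjusted over the list alone (camera adjusted p = 0.00312; adjusted p = 0.346 with an estimated correlation), with Sftpb, surfactant protein B, lower (-3.57) and Ager higher (1.06). Interferon response genes gave 12 higher and 0 lower of 26, 15 adjusted over the list alone (camera adjusted p = 8.36e-07; adjusted p = 0.216 with an estimated correlation).

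Collagens gave 3 higher and 2 lower of 18, 6 adjusted over the list alone (camera adjusted p = 0.452). Basement membrane genes gave 8 higher and 3 lower of 22, 13 adjusted over the list alone (camera adjusted p = 0.0336; adjusted p = 0.344 with an estimated correlation), with the laminin chain Lamb1 at 5256 ± 385 against 1599 ± 149 (1.72) and Col4a6 lower (-0.91). That call was lost without PASMC replicate 3 (adjusted p = 0.0545), with the stricter filter (0.0525) and on implied reads without scaling (0.0748), in a range of 0.013 to 0.0748. Elastic fibre genes gave 5 higher and 0 lower of 21, 5 adjusted over the list alone (camera adjusted p = 0.00813; adjusted p = 0.344 with an estimated correlation). Axon guidance genes gave 10 higher and 4 lower of 38, 17 adjusted over the list alone (camera adjusted p = 0.0387; adjusted p = 0.38 with an estimated correlation). This was lost without PASMC replicate 3 (adjusted p = 0.0613) or total_SMC replicate 2 (0.164) or 3 (0.0695) and with the stricter filter (0.0832), in a range of 0.0143 to 0.164. Genes of alveolar duct myofibroblasts gave 2 higher and 5 lower of 11, 7 adjusted over the list alone (camera adjusted p = 0.0459; adjusted p = 0.269 with an estimated correlation), and 12 of 22 alternatives lost that call, in a range of 0.0266 to 0.127. Leaving out 1 library lost it for BSMC replicate 1 (adjusted p = 0.054) or 2 (0.0552), PASMC replicate 1 (0.0511) or 3 (0.053) and total_SMC replicate 1 (0.0569). Hhip was lower in total_SMC (-0.83) and Fgf18, a growth factor of myofibroblasts, fell by 1.42.

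The count of 2539 was 1607, 1597 and 1610 without total_SMC replicate 1, 2 or 3, and 5082 with array weights. The groups did not overlap in 6342 genes (40.5%, where chance gives 10%). After quantile normalization the calls were 1330 higher and 1416 lower.

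The third comparison set total smooth muscle cells against the bronchial cells. Lists of fibroblast and matrix genes were higher in total_SMC, and lists of contractile, striated muscle and leukocyte genes were lower, by camera at the preset correlation. None of these passed with an estimated correlation (adjusted p = 0.176 to 0.426). Pdgfra was at 7386 ± 813 in total_SMC and 325 ± 170 in BSMC (4.62, SE 0.27, adjusted p = 4.83e-07), and Meox2, a mesenchymal homeobox factor, at 1923 ± 79.6 against 184 ± 14.6 (3.38). Lmod1 was at 1488 ± 244 against 3557 ± 120 (-1.27, SE 0.13, adjusted p = 2.13e-05). Of the genes tested 6553 were changed (41.9%), 3706 higher in total_SMC and 2847 lower, and 3697 by at least 2-fold.

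Of 34 contractile genes 1 was higher and 20 were lower, 23 adjusted over the list alone (camera adjusted p = 3.81e-06; adjusted p = 0.349 with an estimated correlation). Arterial and vascular genes gave 2 higher and 10 lower of 20, 12 adjusted over the list alone (camera adjusted p = 0.00176; adjusted p = 0.176 with an estimated correlation), with Kcnk3, a potassium channel that sets resting potential, at 1523 ± 209 against 3809 ± 747 (-1.31). The cardiac list gave 0 higher and 18 lower of 27, 23 adjusted over the list alone (camera adjusted p = 1.67e-09; adjusted p = 0.349 with an estimated correlation), with Tnnt2 at 368 ± 47.0 against 1443 ± 224 (-1.96). Cspg4 was lower in total_SMC (-1.51, SE 0.26, adjusted p = 0.000892). Chrm2 was higher by 0.92 (SE 0.31, adjusted p = 0.0329), a call lost without BSMC replicate 1 (adjusted p = 0.0752) or 3 (0.102) or total_SMC replicate 2 (0.0961) or 3 (0.115), in a range of 0.00881 to 0.427. Glycolysis genes gave 3 higher and 10 lower of 26, 13 adjusted over the list alone (camera adjusted p = 0.00889; adjusted p = 0.349 with an estimated correlation). Nuclear genes of oxidative phosphorylation gave 0 higher and 39 lower of 62, 49 adjusted over the list alone (camera adjusted p = 2.06e-09; adjusted p = 0.478 with an estimated correlation), and ribosomal protein genes 0 and 30 of 76, 48 adjusted over the list alone (camera adjusted p = 1.67e-09; adjusted p = 0.56 with an estimated correlation). The mean log2 value of both lists was 9.30 and 9.36 in BSMC replicates 1 and 3, the least deep libraries, 8.84 in BSMC replicate 2 and 8.6 to 8.7 in total_SMC.

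Fibroblast genes gave 11 higher and 0 lower of 24 with a median of 0.42, 11 adjusted over the list alone (camera adjusted p = 2.37e-05; adjusted p = 0.349 with an estimated correlation). Scara5 rose by 3.60 and Col14a1, a collagen that coats fibrils, was at 8998 ± 700 against 1222 ± 153 (2.88). Basement membrane genes gave 17 higher and 1 lower of 22, 19 adjusted over the list alone (camera adjusted p = 1.76e-07; adjusted p = 0.176 with an estimated correlation), with Lamb1 higher by 2.98. Collagens gave 10 higher and 1 lower of 18 with a median of 0.52, 12 adjusted over the list alone (camera adjusted p = 0.00149; adjusted p = 0.426 with an estimated correlation). Elastic fibre genes gave 12 higher and 0 lower of 21 with a median of 0.64, 13 adjusted over the list alone (camera adjusted p = 0.00112; adjusted p = 0.349 with an estimated correlation), with Fbn1 at 8780 ± 832 against 1718 ± 81.0. Hedgehog genes gave 10 higher and 1 lower of 12, 11 adjusted over the list alone (camera adjusted p = 0.000152; adjusted p = 0.181 with an estimated correlation), with Boc, a coreceptor, higher by 2.20 and the ligand Ihh lower by -3.46. Axon guidance genes gave 20 higher and 3 lower of 38, 25 adjusted over the list alone (camera adjusted p = 1.81e-05; adjusted p = 0.244 with an estimated correlation), among them the ligand Slit2 (3.80). Airway smooth muscle genes gave 8 higher and 4 lower of 15, 12 adjusted over the list alone (camera adjusted p = 0.239), with Wnt5a higher (2.54) and Lgr6 lower (-0.85).

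All 20 leukocyte genes tested were lower in total_SMC, 20 adjusted over the list alone (camera adjusted p = 1.72e-13; adjusted p = 0.181 with an estimated correlation), and their sum was 517 ± 90.3 CPM against 2085 ± 446. Il1b, a cytokine of myeloid cells, was at 638 ± 149 in BSMC and 2.3 ± 0.6 in total_SMC. Igha (1560 ± 39.2 in total_SMC against 1988 ± 355) and Jchain (1018 ± 127 against 904 ± 400) lay far closer together. Erythroid genes gave 0 higher and 5 lower of 6, 5 adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.349 with an estimated correlation), a call lost after cyclic loess (adjusted p = 0.0652) and without the 2 BSMC libraries of lowest depth (0.111), in a range of 0.00382 to 0.111. Mesothelial genes gave 7 higher and 0 lower of 8, 7 adjusted over the list alone (camera adjusted p = 0.000482; adjusted p = 0.349 with an estimated correlation), with Upk3b at 1955 ± 225 against 320 ± 134.

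The count of 6553 was 4254 without total_SMC replicate 3. The groups did not overlap in 7907 genes (50.5%, where chance gives 10%), and on implied reads without scaling, where the median of all genes moved to 0.23, the calls were 3399 higher and 1552 lower, against 3217 and 4049 after quantile normalization.

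Lists of receptors, potassium channels and neurotrophic genes did not pass the test in any comparison, and held large single changes. Of 56 receptor genes 13 were higher and 10 lower in total_SMC than in PASMC, 28 adjusted over the list alone (camera adjusted p = 0.356). Against BSMC, 17 were higher and 7 lower in PASMC, 29 adjusted over the list alone (camera adjusted p = 0.152, passing in 1 of 22 alternatives, range 0.0402 to 0.418), and 18 and 9 in total_SMC, 27 adjusted over the list alone (camera adjusted p = 0.109, passing in 2 of 22 alternatives, range 0.0278 to 0.311). Ptgfr, the prostaglandin F receptor, was at 2509 ± 111 in total_SMC, 292 ± 39.5 in PASMC and 118 ± 23.7 in BSMC, and Bdkrb1, a bradykinin receptor, at 1314 ± 201, 209 ± 31.3 and 77 ± 18.4. Adra1d, an adrenergic receptor of arteries, was at 94.7 ± 18.4, 427 ± 118 and 637 ± 49.9. Of 39 potassium channel genes 8 were higher and 2 lower in PASMC than in BSMC, 14 adjusted over the list alone (camera adjusted p = 0.0706). That test passed in 5 of 22 alternatives, among them the one without BSMC replicate 3 (adjusted p = 0.0379; range 0.0342 to 0.179). In total_SMC against PASMC 6 were higher and 11 lower, 18 adjusted over the list alone (camera adjusted p = 0.148, with a median of -0.23), among the latter Kcnmb1, a subunit of the calcium-activated channel (-1.12), and Kcnab1 (-1.76). Abcc9, a subunit of ATP-sensitive channels, was at 4398 ± 390 in total_SMC, 2576 ± 505 in PASMC and 750 ± 319 in BSMC. In total_SMC against PASMC, neurotrophic genes gave 4 higher and 4 lower of 14, 9 adjusted over the list alone (camera adjusted p = 0.732): the receptor Ntrk2 rose by 2.73 and the ligand Nrtn fell by 1.38.

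The lists in this paragraph did not pass the test. Between PASMC and BSMC, Wnt genes gave 12 higher and 2 lower, 17 adjusted over the list alone (camera adjusted p = 0.151). All values that follow compare total_SMC with BSMC. Wnt genes gave 19 higher and 8 lower of 43, 28 adjusted over the list alone (camera adjusted p = 0.054), with the receptor Fzd4 at 2882 ± 231 against 312 ± 66.2. That test passed in 9 of 22 alternatives (0.0225 to 0.201), among them those without BSMC replicate 3 (adjusted p = 0.0315) and PASMC replicates 1 (0.0491) and 2 (0.0437). Genes of BMP and TGF-beta signalling gave 20 higher and 14 lower of 44, 36 adjusted over the list alone (camera adjusted p = 0.727), with the ligand Gdf10 higher by 2.83. Disease genes of pulmonary arterial hypertension gave 9 higher and 3 lower of 20, 12 adjusted over the list alone (camera adjusted p = 0.28), with the voltage-gated channel Kcna5 lower (-1.11). Developmental transcription factors gave 10 higher and 19 lower of 64, 31 adjusted over the list alone (camera adjusted p = 0.25), with a median of -0.20, a mean of 0.02 and a negative direction of the test; Foxc1 fell by 1.12. Notch genes gave 5 and 5 of 20, 11 adjusted over the list alone (camera adjusted p = 0.647), with a median of -0.14, a mean of 0.11 and a negative direction of the test, and the target Hey2 fell by 1.12. Pericyte genes gave 5 higher and 10 lower of 17, 15 adjusted over the list alone (camera adjusted p = 0.28), with Cox4i2, a hypoxia-related respiratory subunit, at 857 ± 296 in BSMC, 262 ± 10.2 in PASMC and 194 ± 26.3 in total_SMC. Lipid genes gave 2 higher and 5 lower of 9, 7 adjusted over the list alone (camera adjusted p = 0.211), with Plin4, a lipid droplet coat protein, lower (-1.52). Cell cycle genes gave 3 higher and 0 lower of 20, 0 adjusted over the list alone (camera adjusted p = 0.239), and Schwann cell and neuron genes 0 called of 6, 0 adjusted over the list alone (camera adjusted p = 0.47).

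**Figure D3:**
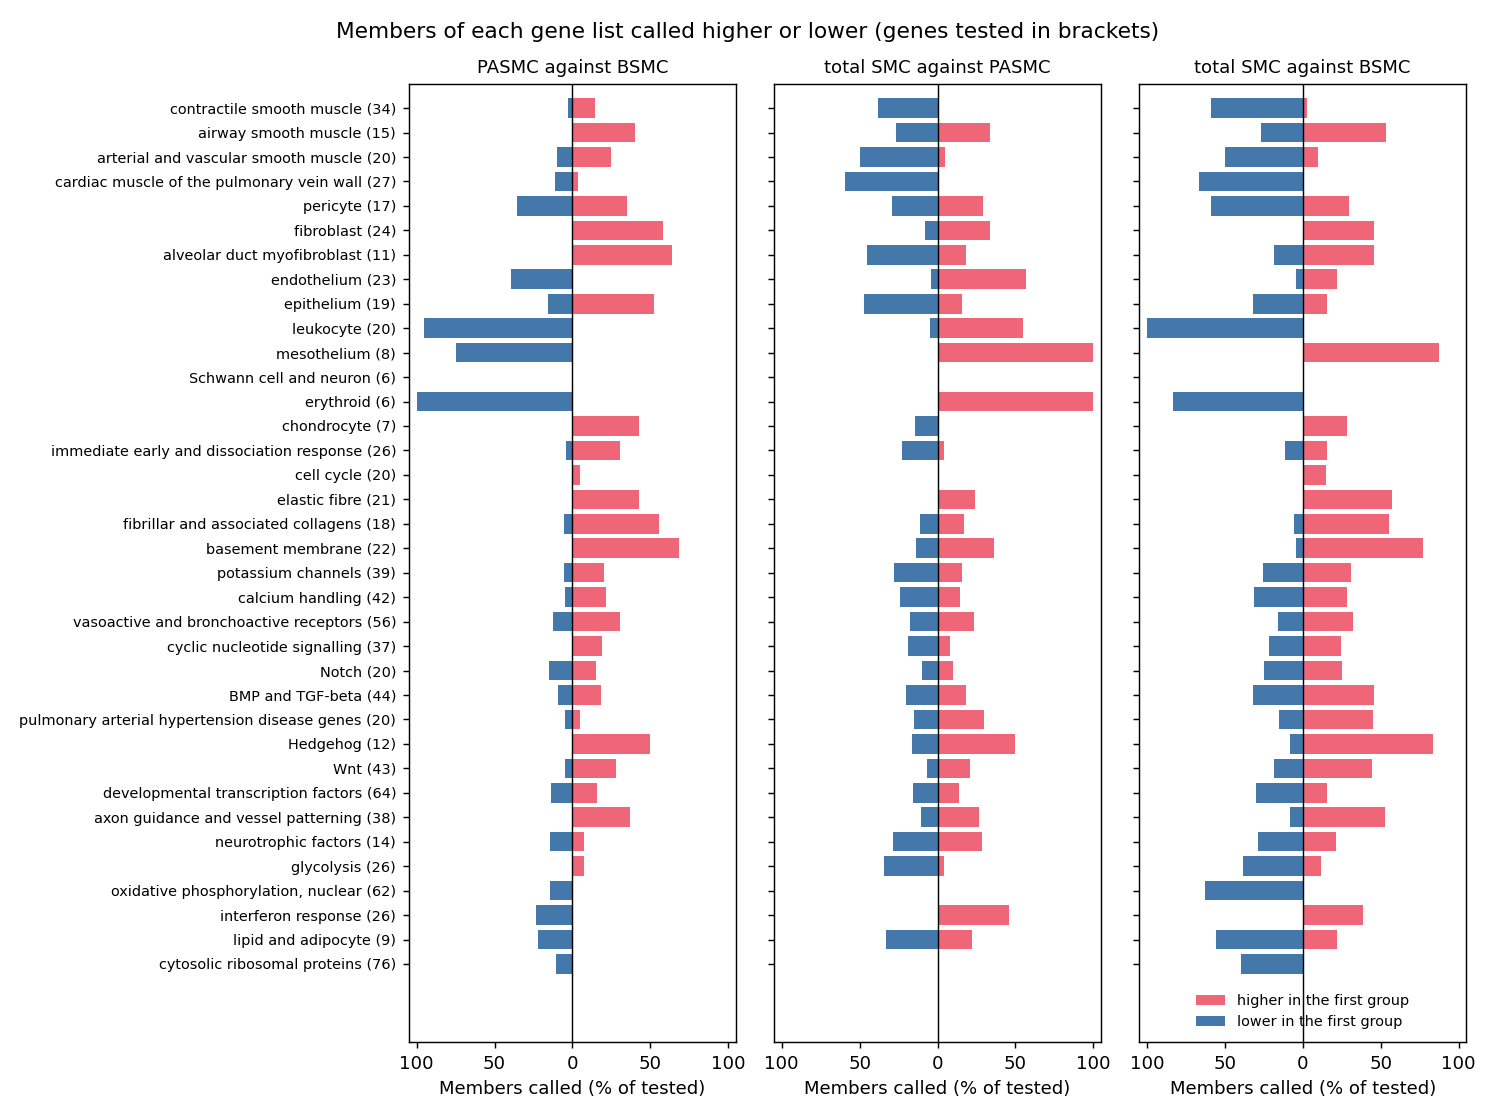
Percent of the tested members of each gene list called higher or lower, in 1 panel per comparison. Leukocyte genes are lower in PASMC than in BSMC (19 of 20), and mesothelial genes higher in total_SMC than in PASMC (8 of 8).

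Each group also had genes that set it apart from both others. In total_SMC 1056 genes were higher than in both, among them Lrrn4, a membrane protein of mesothelium, at 928 ± 47.0 against 25.3 ± 16.7 in PASMC and 33.3 ± 36.1 in BSMC, and the immunoglobulin gene Ighg2b, at 785 ± 229, listed at 0 in all PASMC libraries and at 12.3 ± 2.5 in BSMC. Folh1, a folate hydrolase, was at 210.0 ± 27.5 against 7.3 ± 3.8 and 1.3 ± 2.3. Lower in total_SMC than in both were 753 genes, among them Acta1, the skeletal muscle actin, at 5.7 ± 3.2, against 166, 199 and 755 in the PASMC libraries and 210 ± 74.7 in BSMC, and Ppp1r1b, a phosphatase inhibitor, at 46.7 ± 8.1 against 486 ± 48.0 and 427 ± 35.7. In BSMC 968 genes were higher than in both, among them Ptprc, the pan-leukocyte surface phosphatase, at 573 ± 184 and listed at 0 in all PASMC libraries, and Csf3r, a receptor of neutrophils, at 538 ± 145. In PASMC 203 genes were higher than in both: Slc34a2, a phosphate transporter of alveolar cells, was at 918 ± 138 against 171 ± 54.5 in BSMC and 43.7 ± 9.1 in total_SMC, and Arc, an activity-induced gene, at 742 ± 109 against 161 ± 106 and 156 ± 55.9.

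Counted after the values were seen, 1618 genes were lower in BSMC than in both others and 325 lower in PASMC. The former was 3084 without BSMC replicate 2 and 824 and 997 without PASMC replicates 1 and 2, and the latter 206 without total_SMC replicate 2.

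The other 4 counts, of total_SMC higher, total_SMC lower, BSMC higher and PASMC higher, compare with 348.2, 194.5, 252.7 and 140.9 for independent lists, and simulations without any effect gave means of 0, 0, 0.01 and 0 over 100 runs. Each pair of contrasts shares 3 libraries, which adds to the overlap and was not separated from it. Without total_SMC replicate 1, 2 or 3 the count higher in total_SMC was 632, 600 or 584. The count higher in BSMC was 246, 2002 and 287 without BSMC replicates 1, 2 and 3, 502 and 523 without PASMC replicates 1 and 2, and 573 without total_SMC replicate 3. The count higher in PASMC was 344 without BSMC replicate 2, 85, 102 and 114 without PASMC replicates 1, 2 and 3, and 114 and 127 without total_SMC replicates 1 and 3.

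**Figure D4:**
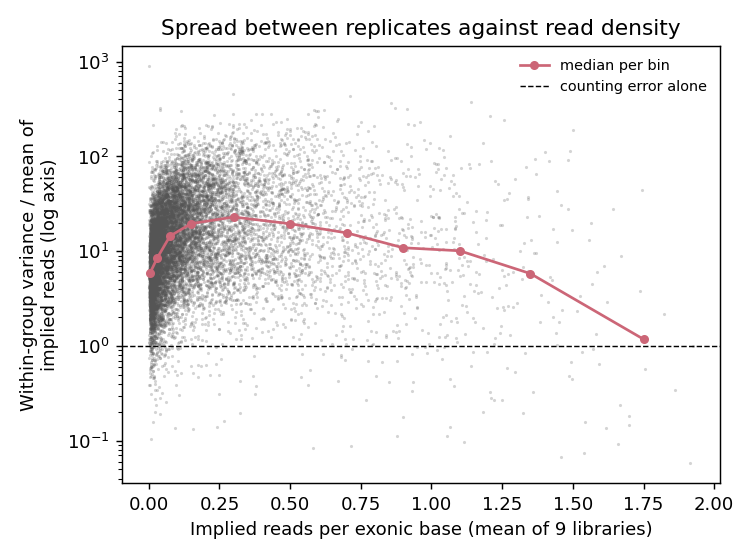
Variance over mean of implied reads within groups, on a log axis, against implied reads per exonic base, on a linear axis, 1 point per gene. The median of each bin is in red and counting error alone is a dashed line. The median falls from 22.97 at 0.2 to 0.4 reads per base to 1.18 above 1.5.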

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

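Counts past the threshold that moved by more than 1.5 times are given here. PASMC against BSMC gave 3451, 1931 at 2-fold or more, 1926 with only the 2 groups in the fit, 1376 without the 2 BSMC libraries of lowest depth, and 1701 to 6364 leaving out 1 library. Total_SMC against PASMC gave 2539, 1656 at 2-fold or more, 5082 with array weights, 4345 with only the 2 groups, 4283 without the 2 BSMC libraries, and 1597 to 3205 leaving out 1 library. Total_SMC against BSMC gave 6553, 3697 at 2-fold or more, 3594 without the 2 BSMC libraries, and 4254 to 8056 leaving out 1 library. In the fit without the 2 BSMC libraries the remaining BSMC library was assumed to vary like the other groups. A fold limit gives fewer calls by construction, but leaving out a library did not always do so. For PASMC against BSMC the calls were 1701 without PASMC replicate 1 and 6364 without BSMC replicate 2. For total_SMC against PASMC they were 1597 without total_SMC replicate 2 and 3205 without BSMC replicate 2. PASMC against BSMC had more calls than total_SMC against PASMC in the main fit (3451 and 2539). With only the 2 groups in the fit it had fewer (1926 and 4345). Apart from the fold limit, the cause of these moves was not tested.

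Genes higher in total_SMC than in both others numbered 1056, 654 at 2-fold or more, 1879 with array weights, 1706 with only the 2 groups, and 584 to 1336 leaving out 1 library. Genes lower in total_SMC numbered 753, 390 at 2-fold or more and 1149 with array weights. Genes higher in PASMC numbered 203, 95 at 2-fold or more, 399 with array weights, and 85 to 344 leaving out 1 library. Genes higher in BSMC numbered 968, 516 at 2-fold or more, 1626 after quantile normalization, 1483 after cyclic loess, 454 on implied reads, 565 with only the 2 groups, 101 without the 2 BSMC libraries, and 246 to 2002 leaving out 1 library.

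The split of higher against lower calls of PASMC against BSMC was 1337 and 490 without BSMC replicate 1, 1697 and 602 without replicate 3, and 1086 and 290 without both. Total_SMC against BSMC gave 2443 and 1151 without both. No shared call changed direction in any scaling. With the replicate number as a block the counts were 3287, 2286 and 6350. The numbers did not pair the libraries: the correlation of deviations ran from -0.124 to 0.136 for libraries of the same number and from -0.19 to 0.14 for others. The planned DESeq2 test was not run. Over all alternatives 137 counts stayed within 1.5 times and 46 moved; of list tests 2285 kept their call, 42 newly passed and 40 were lost; of named genes 9817 kept it, 9 newly passed and 481 were lost.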

Other observations

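The tests on the patterns below were all written after the results had been seen, as were the 4 added alternatives. In PASMC against BSMC, Trpc6, a calcium-permeable channel, was at 44.3 ± 21 against 216 ± 24.7 (-2.36, limma adjusted p = 0.000471). Cyclic nucleotide genes gave 7 higher and 0 lower in PASMC, 7 adjusted over the list alone (camera adjusted p = 0.0203; adjusted p = 0.342 with an estimated correlation). That call was lost without the 2 BSMC libraries of lowest depth (adjusted p = 0.0975), in a range of 0.00545 to 0.0975 over all alternatives. Ifi202b, an interferon-inducible gene whose expression differs between mouse strains, was listed at 0 in all BSMC and PASMC libraries and at 295, 198 and 378 in total_SMC.

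The densest genes varied less between libraries of a group than other genes, with a median near counting error and single genes far below it. Implied reads of Sparc in PASMC had an SD of 5.0 where counting gives 63.0, and those of Cnn1 in BSMC 7.8 against 54.6. Others lay above counting error, such as Acta2 in total_SMC (204.5 against 56.2). Reads at the same position and strand counted once could give the reduced spread. Of genes above 1.5 implied reads per exonic base, 46.43% had a variance under the mean, against 0.83% at 0.2 to 0.4 and 57.7% for counting error alone. The highest density was 1.93, in Ccn1. Library factors applied to capped genes would shift them between groups, and the median shifts predicted from the factors differed from those observed by at most 0.02. For ribosomal and respiratory chain genes the median difference between PASMC and BSMC was -0.44 (SD between BSMC libraries 0.29). The factors would give -0.23 in genes at the limit. Only 1 of 76 ribosomal and 8 of 62 respiratory chain genes were near it, so the factors could act in full on few of them. Cyclic loess, which removes trends with abundance, left -0.52. Both lists passed camera in 22 of 22 alternatives, but not with an estimated correlation (adjusted p = 0.514 for ribosomal and 0.473 for respiratory chain genes). Without the 2 BSMC libraries of lowest depth the medians of these lists were -0.09 and -0.11, so a biological difference and an effect of depth cannot be told apart.

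Leukocyte genes were higher in BSMC than in PASMC and total_SMC. Leukocytes carried into the BSMC sorts cannot be told apart from another cause, since the count of 19 of 20 tested genes higher than in PASMC and 20 of 20 higher than in total_SMC is the pattern itself. The cells had already been sorted by fluorescence, and whether leukocytes passed the sorts was not tested. A lower share of smooth muscle alone was not settled. Against PASMC, fibroblast genes gave 14 lower and 0 higher in BSMC, and epithelial genes 10 lower and 3 higher. Endothelial genes gave 0 lower and 9 higher, mesothelial genes 0 and 6, and erythroid genes 0 and 6. These counts cannot decide, since they also depend on which other cells the PASMC sorts held. A single leukocyte mixture in BSMC and total_SMC was tested only on Igha, Igkc and Jchain, which are in none of the lists. The leukocyte list had a median of -4.33 in total_SMC against BSMC (interquartile range 1.84), and Igha, Igkc and Jchain a median of -0.18. These values argue against a single mixture for the genes named, which were compared after the results had been seen. They do not describe all immunoglobulin genes, since Ighg2b was higher in total_SMC than in BSMC.

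Of 15 airway smooth muscle genes 6 were higher in libraries labelled PASMC, a list call lost with an estimated correlation (adjusted p = 0.342) and without BSMC replicate 2 (0.158; range over alternatives 2.81e-05 to 0.158). Exchanged labels could give this and cannot be told apart from a true difference by the arterial and vascular list, with a median of 0.02. The SE over its 20 genes was 0.13, which is not the SE of the fit. Of the genes named in the lines, Cspg4 lay in the direction of the labels (0.40, limma adjusted p = 0.268, range over alternatives 0.135 to 0.569). Chrm2 lay against them (0.98), with overlap between the groups. It passed in 12 of 22 alternatives (limma adjusted p from 0.00963 to 0.535). Library factors acting on genes at the limit would move PASMC against BSMC by -0.23. The 15 tested airway genes had a median of 0.48, the opposite direction, or 0.37 after cyclic loess. The SE over these genes was 0.20, which treats them as independent. Only 2 of them were near the limit, so the factors could act on few of them and the median is no test of the factors. A Cspg4 line that also marks airway muscle remains possible and was not tested.

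The statistic for splits of 9 libraries was redefined after a version of it had been seen. For pairwise counts the 10 splits of 6 libraries were too few for a share under 0.05, with 1 split as large as the real 3451, 2539 and 6553 and a highest other of 0 in each. Over 100 drawn splits of the 9 libraries, each count was set against the most genes of any group in a split. For genes higher in total_SMC (1056, highest other 529) and higher in BSMC (968, highest other 529), 1 split was as large, the real one. This does not exclude chance, since of 99 other splits only the 8 that kept a real group whole gave any genes. Without BSMC replicate 1 or 3 the count higher in BSMC was 246 or 287, under 529. For genes lower in total_SMC (753, highest other 941) 4 splits were as large, and for genes higher in PASMC (203, highest other 529) 5 were. The other splits as large each kept the libraries of a real group together, so they hold a group difference and decide little, and splits without a whole group gave at most 0 genes, as did simulations without any effect for these 2 results. For the list tests 1 split reached the real 51, but the highest other was 50 and the median of the others 34, and leaving out 1 library gave 47 to 54, so this margin of 1 call says little.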
